A study of Drosophila melanogaster with 3 samples.

How the data were processed

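RNA from whole heads of adult Drosophila melanogaster was measured on 3 Affymetrix arrays, with 1 array for each of 3 genotypes. All flies carried the MB247-Gal4 driver, which acts in the mushroom bodies, together with a temperature-sensitive Gal80 repressor under a tubulin promoter. The control carried the driver and repressor alone, PKA-DN flies added a dominant-negative form of protein kinase A (PKA), and PKA-CA flies added a constitutively active form. Per the labels' protocols, flies were reared at 18 °C and moved to 32 °C for 12 to 16 h, which inactivates the repressor and lets Gal4 drive the transgene. Heads were taken at 4 to 6 days of age, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA. The submitted design text pairs raised and lowered PKA activity with the transgenes in the opposite order to their names; here PKA-DN is taken as the form that lowers activity and PKA-CA as the form that raises it. The sources used here do not say which coding sequences the transgenes carried.

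The deposited values were linear array intensity, 1 signal per probe set, made with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. Each array held 18952 probe sets, and the mean signal after leaving out the highest and lowest 2% of probe sets was 500 on every array, so the arrays had been scaled to a common mean before deposit. The values were used as deposited, with no further normalization, and were placed on the log2 scale with no added constant. MAS5 detection calls were not used here, so dim probe sets were judged against the 99 Drosophila negative-control probe sets, after 1 of 100 with a signal above 1000 was left out. The highest negative-control signal was 77.0 on the control array, 77.8 on the PKA-DN array and 70.9 on the PKA-CA array.

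Probe sets were named through the platform's gene table, which listed 14049 of them. Of these, 13646 had a single gene symbol, 402 had several and 1 had none; 4903 were not listed and are unnamed here, 4720 of which were not Affymetrix controls. Symbols were updated through RefSeq gene identifiers of the assembly Release 6 plus ISO1 MT for 13543 probe sets, and the table's own symbol was kept for 103. That assembly served for names, gene lengths and neighbouring genes only, and no coordinates are given. The 11981 named genes included 1094 with several probe sets, for which the probe set with the highest mean log2 signal over the 3 arrays was used. Genes in the upper 50% by mean log2 signal were compared, which kept 5991 genes with a mean signal above 254. Some genes of interest, among them Pka-C1, Pka-R2, ninaE, Mef2, Fas2 and DptA, were on no probe set with a single name and were not analysed here.

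Each gene was described by its signal on each array and by log2 ratios for 3 comparisons: PKA-DN over control, PKA-CA over control and PKA-CA over PKA-DN. With 1 array per group there is no replicate error and no test, and the number of arrays limits the precision of every value. Genes were counted at 2-fold or more each way. To look for responses ordered by PKA activity, genes with the control array between the other arrays and both steps of 1.5-fold or more were counted, beside the same counts with PKA-DN or PKA-CA in the middle. The ratios of both PKA arrays share the control array. Their correlation, covariance and overlap were therefore set beside 200 simulations of unchanged groups sharing a control, with noise drawn within 20 bins of mean signal from the deviations of the 3 arrays, which also hold any real differences.

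In total, 30 gene lists were fixed in advance. They covered the PKA and cAMP pathway, activity-regulated genes, mushroom body enriched genes, memory genes, circadian clock genes, neurotransmitter receptors, ion channels, synaptic vesicle release, neuropeptides, glia, phototransduction, odorant-binding and antennal genes, and eye pigment and background markers. Others covered antimicrobial genes, Turandot stress genes, heat shock genes, insulin and nutrient-responsive genes, head fat body, female fat body, muscle, gut enzymes, male reproductive tract, ovary, the roX RNAs of male dosage compensation, cytochrome P450, glutathione transferase and UDP-glycosyltransferase genes, ribosomal proteins, the mitochondrial respiratory chain and reference genes. A list with 3 or more members in the upper 50% was summarised by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. Values below the 2.5th or above the 97.5th percentile are called outside the range of random lists, which 5% of random lists are by construction. After values had been seen, 5 list names were left out because their synonyms pointed to other genes, and marker lists for blood cells and oenocytes were added for the closing tests.

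The genes named are the 10 with the highest and the 10 with the lowest ratio in each comparison with the control, the 5 each way for PKA-CA over PKA-DN, up to 5 each way with the control in the middle, all members of the PKA list in the upper 50%, and up to 4 members of each other list with the largest absolute ratio in a comparison. Other genes named are said to have been chosen after their values were seen.

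The gene lists, the naming rule, the thresholds and the alternatives were set before the data were examined. The alternatives were quantile normalization, cyclic loess, centring each array on its median, adding 16 or 64 before log2, no signal filter or the upper 25%, a 1.5-fold threshold (2-fold for the ordered steps), the mean over all probe sets of a gene, and random lists not matched on signal. Random lists matched on gene length as well, in 5 strata of length and 10 of signal, were added after a trend with gene length had been seen, and a finer matching, in 20 strata of length and 5 of signal, after the percentiles of the coarser one. Without replicates, a list median was called moved under an alternative when it shifted by more than 1 SD of matched random medians, a choice also made after values had been seen.

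Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1, with a random seed of 20. The counting and list steps were tested on data simulated for PKA-CA over control with 5991 genes. At the 2-fold threshold, 6% of genes given a 1.5-fold difference were called, 44% of those given 2-fold, 96% of those given 3-fold and 100% of those given 4-fold, as were 30 of the 5791 genes given none (0.52%). With noise drawn separately for each gene, lists of 20 unchanged genes fell outside the range of random lists in 4% of draws. Of lists shifted by 0.2 on the log2 scale, 91% fell above that range.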

Results

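Gene expression was profiled in heads of adult flies after 12 to 16 h of induction in the mushroom bodies. These are the brain centre for olfactory learning and memory. PKA-DN is taken to lower PKA activity there and PKA-CA to raise it, but activity itself was not measured here. The question was which transcripts follow PKA activity. Each genotype was measured on 1 array, so no value has a replicate error. The mushroom bodies are a small part of the head, and the RNA came from all head tissues.

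The arrays were close to each other. Across 5991 genes the correlation of log2 signals was 0.983 between control and PKA-DN, 0.980 between control and PKA-CA, and 0.978 between PKA-DN and PKA-CA; genes are not independent replicates. Median signals over all probe sets were 89.6, 88.2 and 82.8 on the control, PKA-DN and PKA-CA arrays. RNA integrity measures differed somewhat: the 3'/5' signal ratio of GAPDH was 1.70, 2.06 and 2.0 in the same order, that of actin 1.79, 2.29 and 1.70, and that of eIF-4a 2.51, 2.33 and 3.01. Signals of the spike-in controls on the PKA-DN and PKA-CA arrays, relative to the control array, were 0.69 and 0.79 for bioB. They were 0.69 and 0.72 for cre and 1.15 and 1.27 for dap, so each differed in the same direction on both. Reference genes lay near 0, with medians of -0.10 for PKA-DN and -0.09 for PKA-CA over control, the latter above 0 at 0.04 under quantile normalization. RpL32, for example, had log2 ratios of -0.07 and -0.11, which quantile normalization turned to 0.003 and 0.10, and eIF4A of -0.13 and -0.23. For PKA-CA over PKA-DN the reference median was -0.07, which turned to 0.01 with cyclic loess and 0.05 with quantile normalization.

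Genes of the PKA and cAMP pathway were examined first. On the PKA-CA array most members were slightly higher than on the control array, and on the PKA-DN array most were slightly lower. The pathway list held 30 names, of which 24 had a probe set and 20 were bright enough to compare. For PKA-CA over control 14 members were higher and 6 lower, with a median log2 ratio of 0.16, while for PKA-DN over control 6 were higher and 14 lower, with a median of -0.08. Between the PKA arrays 17 members were higher in PKA-CA and 3 were lower, with a median of 0.26. The medians lay at the 99.5th percentile of random lists for PKA-CA over control, the 6.69th for PKA-DN over control and the 99.98th for PKA-CA over PKA-DN. No member differed by 1.5-fold from the control on either array.

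The regulatory subunit gene Pka-R1 had log2 ratios over control of 0.03 in PKA-DN and 0.40 in PKA-CA, and the catalytic subunit gene Pka-C3 of -0.08 and -0.01. Among genes for cAMP synthesis, the adenylyl cyclase rutabaga (rut), a classical learning gene, had 0.03 and 0.08, Ac76E -0.12 and 0.42, and Ac13E -0.09 and 0.30, and the stimulatory G protein subunit Galphas had 0.07 and 0.10. Among phosphodiesterases, which break down cyclic nucleotides, dunce (dnc) had -0.06 and 0.39, Pde1c -0.54 and 0.11, Pde6 -0.08 and 0.23, Pde9 -0.23 and -0.18, and Pde11 -0.16 and 0.25. The anchoring protein genes were spread, with Akap200 at 0.18 and -0.43, rugose (rg) at -0.50 and 0.02, and spoon at 0.27 and 0.36. The coactivator genes Crtc and nejire (nej) had -0.03 and -0.17, and -0.56 and -0.33. The remaining members were Epac at -0.09 and 0.34, Nf1 at -0.08 and 0.21, Gprk1 at -0.02 and -0.11, and Gprk2 at 0.12 and 0.28. Between the PKA arrays the widest differences were Pde1c at 0.65, Akap200 at -0.61, Ac76E at 0.54 and rg at 0.52 for PKA-CA over PKA-DN. When all probe sets of a gene were averaged, dim ones included, the list medians were 0.03 for PKA-DN over control, 0.10 for PKA-CA over control and 0.06 for PKA-CA over PKA-DN. Single members also took the opposite sign then: in PKA-DN over control nej (0.96), Epac (0.36), Pde9 (0.13) and Pka-R1 (-0.29), and in PKA-CA over control nej (1.13), Pde9 (0.10), Pka-R1 (-0.31), Pde11 (-0.05) and Pde1c (-0.05). The ratios of Pka-C3 in PKA-CA and of Crtc and Gprk1 in PKA-DN crossed 0 when the arrays were centred, and that of rg in PKA-CA under quantile normalization. Pathway genes are long, and against random lists matched on gene length too the median for PKA-CA over control lay at the 93.5th percentile, inside their range; with finer strata of length the median for PKA-CA over PKA-DN lay inside it too, at the 94.5th.

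**Figure D1:**
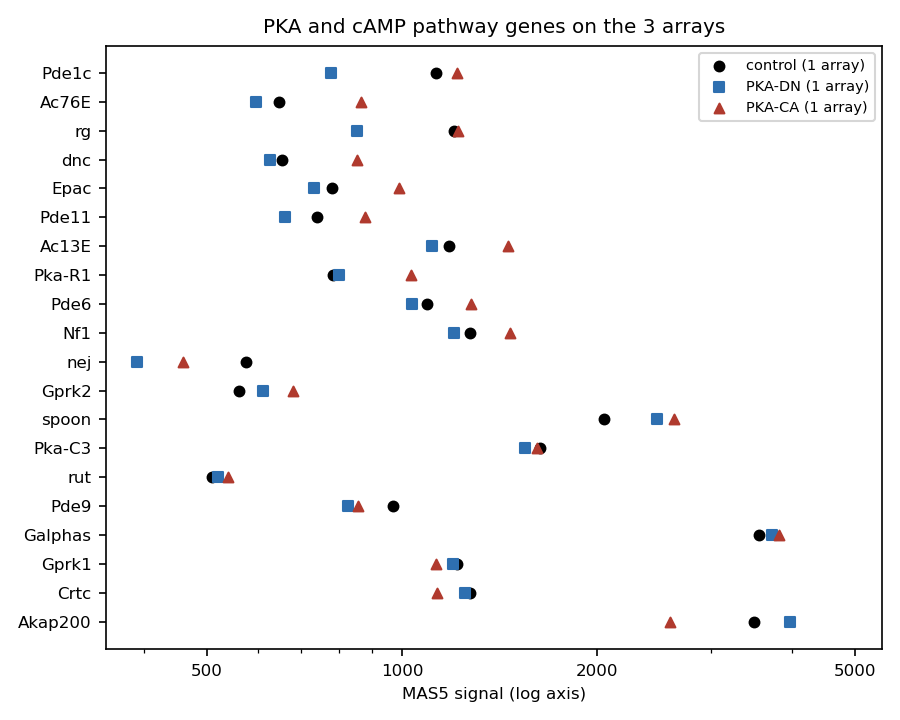
MAS5 signal (horizontal log axis) of the 20 PKA and cAMP pathway genes compared, with 1 point for each of the control, PKA-DN and PKA-CA arrays; genes are ordered by their PKA-CA over PKA-DN ratio, with the highest at the top. The PKA-CA point lies right of the PKA-DN point for 17 genes, from Pde1c (log2 ratio 0.65) downwards, and left of it for 3, among them Akap200 (-0.61).

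The next comparison was PKA-DN with control, which asks what differs when PKA activity is lowered. Several antimicrobial peptide genes were far higher in PKA-DN heads, although the antimicrobial list as a whole was split, with 6 members higher and 6 lower. The drosomycin-like gene Drsl5 had a signal of 5383 against 1140 in the control (log2 ratio 2.24), Diptericin B (DptB) 2384 against 606 (1.98), and Drsl4 and Defensin (Def) had ratios of 1.45 and 1.41; Drsl4 and Drsl5 were on no list. Of 5991 genes, 19 were at least 2-fold higher and 17 at least 2-fold lower. The lower genes included pathetic (path), an amino acid transporter gene, at 736 against 2952 (-2.0), and both prophenol oxidase genes compared, PPO2 at -1.53 and PPO1 at -1.35, which encode melanization enzymes of crystal cells, a blood cell type. A list of 11 other blood cell genes, drawn up after values had been seen, had a median of -0.34 in PKA-DN and 0.15 in PKA-CA.

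The highest ratio in PKA-DN belonged to Zip102B, a zinc transporter family gene, at 694 against 81.6, 8.50-fold or 3.09 on the log2 scale; its control signal was barely above the highest negative control, so the fold is imprecise. Pepck2, encoding a phosphoenolpyruvate carboxykinase, followed at 1452 against 297 (2.29). The rest of the 10 highest were CG8539 at 1.59, alpha-Est2 at 1.43, CG9662 at 1.40 and CG3348 at 1.35. The other genes among the 10 lowest were CG33296 at -1.87, CG3308 at -1.43, CG9512 at -1.41, CG5676 at -1.26, CG34227 at -1.26, the fatty acid elongase family gene Elovl7 at -1.23 and Pgant4 at -1.17.

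By group, 4 of 12 antimicrobial and immune-induced genes were 1.5-fold or more higher in PKA-DN, namely DptB, Def, Drosomycin (Drs, 0.92) and Metchnikowin (Mtk, 0.70), but 6 members were lower and the list median of 0.04 (-0.001 in the upper 25% by signal) lay within the range of random lists, at the 70.8th percentile. UDP-glycosyltransferase genes, which conjugate sugars to small molecules, were higher, with 10 of 13 above the control and a median of 0.35 at the 100th percentile (0.15 in the upper 25% by signal). Examples were Ugt317A1 at 0.60, Ugt301D1 at 0.53 and Ugt35C1 at 0.52. Muscle genes had a median of 0.22 (99.99th percentile), led by the LIM-domain gene Mlp60A at 1.06 (-0.002 when its probe sets were averaged), Act87E at 0.76 and paramyosin (Prm) at 0.64, while TpnC41C had -0.79. Neuropeptide genes had a median of 0.17 (99.97th percentile), with Trissin at 0.41, NPF at 0.40, Ilp5 at 0.36 and Pdf at -0.33.

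Neurotransmitter receptor genes were lower in PKA-DN heads: 18 of 21 lay below the control, with a median of -0.22 at the 0.01th percentile, which was -0.14 in the upper 25% by signal and -0.11 when probe sets were averaged. Among them were the histamine-gated channel ort at -0.54, GluClalpha at -0.46 (0.47 when its probe sets were averaged) and nAChRalpha2 at -0.46, against 5-HT2A at 0.40. The GluClalpha average was turned by a probe set with a mean signal of 20.7, below the highest negative control, at 3.15. Its other probe sets had -0.40 and -0.42. Female fat body genes had a median of -0.27 (0.555th percentile), with the yolk protein genes Yp3 at -0.33, Yp1 at -0.29 and Yp2 at -0.26 and fit at 0.20. Ribosomal protein genes had -0.11 (0.895th percentile; RpL41 -0.29, RpL39 -0.26), with 29 of 33 lower. Under quantile normalization the female fat body and ribosomal medians moved to -0.02 and -0.01. Glutathione transferase genes had -0.10 (1.77th percentile; GstD9 -0.59, GstD1 -0.38). Glial genes had -0.11 (1.92nd percentile), led by ebony (e) at -1.15 and astrocytic leucine-rich repeat molecule (alrm) at -0.69, but lay inside the range of random lists matched on length as well, at 3.38 (1.92 with finer strata of length).

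The remaining lists were within the range of random lists in PKA-DN over control. Ion channels had a median of -0.09, with the sodium channel gene para at -0.70 and Elk at 0.41, synaptic vesicle release genes -0.06 (Rbp -0.65, or 0.48 when its probe sets were averaged, and Rim -0.54), memory genes -0.07 (Dop2R -0.40 and aPKC -0.34, or 0.08 and 0.02 averaged), mushroom body enriched genes -0.06 (trio -0.30, scb 0.21) and circadian clock genes -0.05 (Pdp1 -0.63, Usp8 0.55). Cytochrome P450 genes had -0.05 (below the range at 2.48 when matched on length in finer strata), with Cyp6a8 at 1.33 and Cyp9c1 at 1.08, activity-regulated genes 0.05 (CG13868 0.69), head fat body genes 0.02 (Lsp2 0.68), odorant-binding and antennal genes 0.02 (Obp99a 1.18, Obp8a 0.87) and eye pigment and background markers -0.19 (ry -0.40). Heat shock genes, at -0.03 (Hsp26 -0.61, Hsp68 -0.53), insulin and nutrient-responsive genes, at -0.02, mitochondrial respiratory chain genes, at -0.01, and phototransduction genes, at -0.06 (rdgA -0.45), each crossed 0 under at least 1 other scaling. As all ratios in this comparison rest on 1 array each, a difference between flies, extractions or hybridizations is included in each of them.

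**Figure D2:**
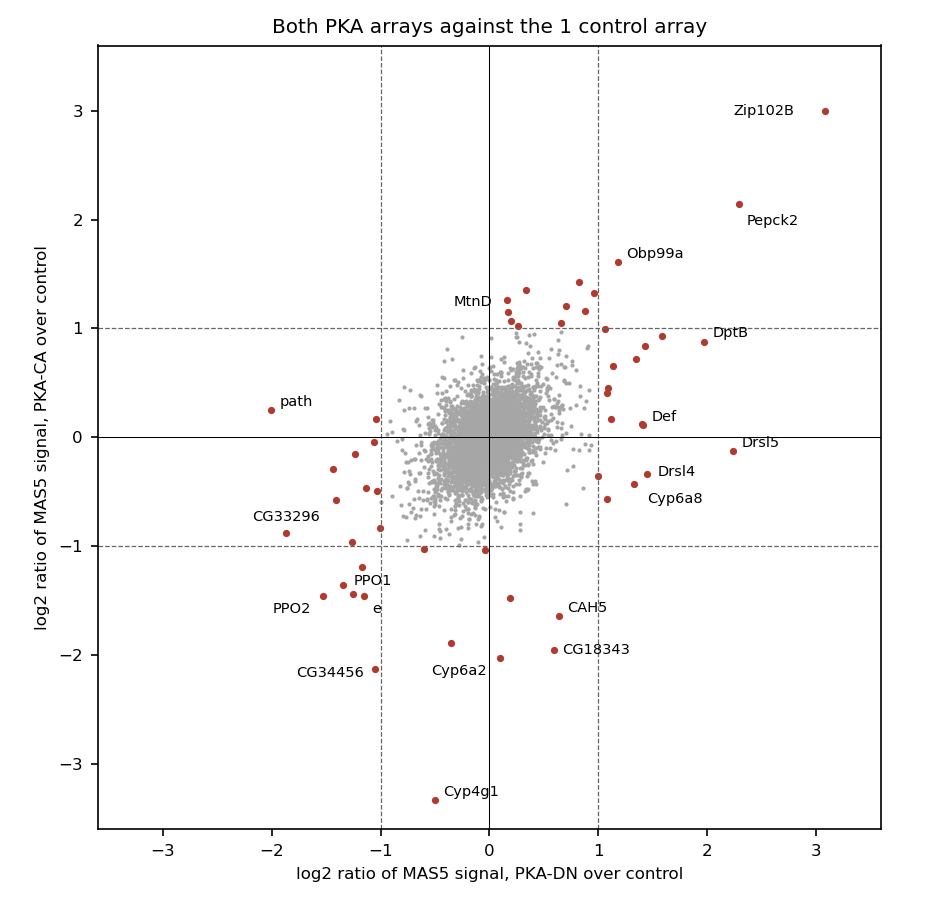
Log2 ratio of MAS5 signal over the control array for each of 5991 genes, PKA-DN on the horizontal axis and PKA-CA on the vertical axis; red points differ 2-fold or more on at least 1 array and dashed lines mark 2-fold. Zip102B (3.09 and 3.0) and Pepck2 (2.29 and 2.14) lie high on both axes, Drsl5 (2.24 and -0.13) on the horizontal axis, and Cyp4g1 (-0.50 and -3.33) low on the vertical axis.

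PKA-CA was compared with control to ask what differs when PKA activity is raised. Cytochrome P450 genes (36 of 44) and glutathione transferase genes (19 of 24) were mostly lower in PKA-CA heads. Cyp4g1, the oenocyte P450 of cuticular hydrocarbon synthesis, had a signal of 76.0 against 766 in the control (10.1-fold, log2 ratio -3.33), close to the highest negative control on that array, so the fold is imprecise, and the xenobiotic-induced Cyp6a2 had 482 against 1968 (-2.03). Zip102B (654; log2 ratio 3.0) and Pepck2 (1310; 2.14) were again the highest, followed by the odorant-binding protein gene Obp99a at 3934 against 1288 (1.61). In total, 13 genes were at least 2-fold higher and 14 at least 2-fold lower, while 30 of 5791 genes simulated without a difference passed 2-fold, from noise that also holds any real differences between the arrays.

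The other genes among the 10 highest were the peroxiredoxin gene Prx6c at 1.43, CG11425 at 1.35, CG10962 at 1.32, the metallothionein gene MtnD at 1.27, the axon guidance receptor gene robo1 at 1.20, CG3097 at 1.16 and Srg1 at 1.15. The other genes among the 10 lowest were CG34456 at -2.13, CG18343 at -1.95, CG4757 at -1.89, the carbonic anhydrase gene CAH5 at -1.64, CG13022 at -1.48, ebony (e), a beta-alanyl amine synthase gene of pigmentation and glia, at 291 against 800 (-1.46), PPO2 at -1.46 and CG34227 at -1.44.

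Of the P450 genes lower in PKA-CA than in the control 7 were so by 1.5-fold or more, and the list median of -0.27 (-0.16 with no signal filter) was below all random lists (percentile 0). After Cyp4g1 and Cyp6a2 came Cyp6a13 at -0.93 and Cyp9h1 at -0.92. Glutathione transferase genes had a median of -0.17 (0.13th percentile), led by GstE11 at -0.99 and GstD9 at -0.85. Female fat body genes were lower too, at -0.51 (0.05th percentile; Yp3 -0.72, or -0.39 under quantile normalization, Yp1 -0.56), as were ribosomal protein genes at -0.22 (1.24th percentile; RpL41 -0.48, RpL28 -0.39), and quantile normalization moved these medians to -0.12 and -0.005. RpL41 and Yp3 are among the brightest genes on these arrays.

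Muscle genes were higher in PKA-CA, with 14 of 16 above the control and a median of 0.37 at the 100th percentile; Mlp60A had 0.99 (0.25 when its probe sets were averaged), the troponin T gene upheld (up) 0.87, Prm 0.80 and Act87E 0.70. Mushroom body enriched genes had a median of 0.29 (99.98th percentile), with 9 of 11 higher, including the integrin gene scb at 0.48, drk at 0.43, dnc at 0.39 and toy at 0.33. Neuropeptide genes had 0.22 (99.97th percentile), led by the insulin-like peptide gene Ilp5 at 0.94 and corazonin (Crz) at 0.53, with Nplp2 at -0.37. Mitochondrial respiratory chain genes had 0.04 (99.6th percentile; COX7AL2 0.69; 0.02 with no signal filter and 0.09 with arrays centred), inside the range of random lists that were not matched on signal, at 88.0.

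Memory genes had a median of 0.14 (98.9th percentile; 0.07 in the upper 25% by signal), among them staufen (stau) at 0.63 and Nmdar1 at 0.42. Receptor genes had 0.13 (99.4th percentile; 0.21 in the upper 25%) with 17 of 21 higher, including nAChRbeta1 at 0.44 and nAChRalpha3 at 0.42, whereas ort had -0.55. Ion channel genes had 0.14 (99.1st percentile; 0.07 with no signal filter, 0.05 when probe sets were averaged), with Hyperkinetic (Hk) at 0.63 (0.30 averaged) and tipE at 0.51 but Elk at -0.69 and para at -0.65. Insulin and nutrient-responsive genes had 0.13 (98.2nd percentile), with Pepck2 at 2.14 and Ilp5 at 0.94 but Lip4 at -0.66 and Pepck1 at -0.35. Matched on gene length as well, these medians lay inside the range of random lists, at percentiles of 91.1 for memory, 90.4 for receptors, 94.1 for ion channels and 95.6 for insulin genes.

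Within the range of random lists in PKA-CA over control were synaptic vesicle release genes at 0.11 (Rbp -0.56, Syt7 0.44), UDP-glycosyltransferase genes at 0.14 (9 of 13 higher; Ugt36E1 0.69; -0.08 in the upper 25% by signal), activity-regulated genes at 0.08 (CG13868 0.64, CG8910 0.56), circadian clock genes at 0.08 (Pdp1 0.39, jet 0.36), glial genes at -0.07 (e, alrm -0.74, loco -0.57), head fat body genes at -0.14 (Lsd-1 -0.43), heat shock genes at -0.12 (Hsp26 -0.49, Hsc70-4 -0.48) and phototransduction genes at 0.02 (Pdh -0.47; -0.02 when probe sets were averaged). Antimicrobial genes, at -0.02 with DptB at 0.88 and Listericin at -0.48, odorant-binding genes, at 0.00 with Obp83cd at 0.91 and Obp19b at -0.74, and eye pigment markers, at -0.03, crossed 0 under another scaling. Matched on gene length as well, UDP-glycosyltransferase genes lay above the range, at 98.6 (97.6 with no matching), and head fat body genes below it, at 2.23; with no matching vesicle release genes lay above it, at 98.0. Where Drsl5 and Def were far above the control in PKA-DN, their ratios here were -0.13 and 0.11.

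PKA-CA over PKA-DN is the widest intended contrast in PKA activity and does not involve the control array. Immune and P450 genes were lower in PKA-CA than in PKA-DN, and several lists of neuronal genes were higher. The path transporter gene had the highest ratio at 2.25, and Cyp4g1 the lowest at -2.83. Altogether 19 genes were at least 2-fold higher in PKA-CA and 23 at least 2-fold lower, and the 19 became 9 when 64 was added to each signal. After path came the noncoding RNA lncRNA:alphagamma-element:CR32865 at 1.24, the amphiphysin gene Amph at 1.21, CG10814 at 1.20 and spinophilin (Spn) at 1.18, whose other probe sets had -0.20 and 0.35 (mean 0.44). After Cyp4g1 came CG18343 at -2.54, Drsl5 at -2.37, CAH5 at -2.29 and Cyp6a2 at -2.13.

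Antimicrobial genes had a median of -0.25 (0.05th percentile) with 9 of 12 lower, led by Def at -1.30, DptB at -1.10 and Drs at -1.03. Cytochrome P450 genes had -0.20 (percentile 0), with 6 of 44 at least 2-fold lower, among them Cyp6a8 at -1.77 and Cyp9c1 at -1.64. Head fat body genes had -0.24 (0.2nd percentile; AkhR -0.45, Lsd-1 -0.44), and glutathione transferase genes -0.11 (1.93rd percentile; GstE11 -0.71; -0.20 with no signal filter), the latter at 12.3 when matched on length.

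Genes of neurons were higher in PKA-CA than in PKA-DN across several lists. Receptor genes had a median of 0.25 (99.99th percentile; 0.15 in the upper 25% by signal) with 19 of 21 higher, led by nAChRalpha3 at 0.82 and nAChRbeta1 at 0.58. Ion channel genes had 0.26 (100th percentile; 0.17 when probe sets were averaged) with 17 of 20 higher, among them Shaker (Sh) at 0.52 and slowpoke (slo) at 0.49, and Elk at -1.10. All 11 mushroom body enriched genes were higher, with a median of 0.26 (99.8th percentile; trio 0.59, dnc 0.45, ey 0.33), and so were 15 of 18 memory genes at 0.20 (99.9th percentile; 0.12 in the upper 25%; stau 0.78, Dop2R 0.54) and 21 of 24 synaptic vesicle release genes at 0.14 (99.6th percentile; Rim 0.65, or 0.41 averaged, Syt7 0.58). The ratio also went with gene length across all genes, with a median of -0.06 in the fifth of genes with the shortest span and of 0.14 in the fifth with the longest. When random lists were matched on length too, receptors (99.1), ion channels (99.6) and the PKA list (98.0) stayed above the range, and mushroom body (93.6), memory (95.3) and synaptic vesicle release genes (91.3) lay within it; with finer strata the PKA list also lay within it, at 94.5.

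Muscle genes had 0.20 (99.8th percentile; 0.09 in the upper 25% by signal), with TpnC41C at 0.87 and up at 0.60; the third largest member, Sap47 at 0.44, encodes a synapse-associated protein. Mitochondrial genes had 0.04 (99.6th percentile; 84.8 without matching on signal), and 0.09 under quantile normalization. The other lists lay within the range of random lists: circadian clock genes at 0.15 (97.4th percentile; 97.9 with no matching on signal), though the clock transcription factor gene Pdp1 had 1.02, cwo 0.64 and Pdf 0.59, neuropeptides at 0.06 (Nplp3 -0.45), insulin genes at 0.04 (InR 0.55), activity-regulated genes at 0.08 (hry 0.27), glia at 0.03 (CG6126 -0.43; -0.01 with no signal filter), eye pigment markers at 0.03 (ry 0.41; -0.27 when probe sets were averaged), heat shock genes at -0.07 (Hsp68 0.44; 0.02 in the upper 25% by signal), odorant-binding genes at -0.11 (Obp83cd 0.89), UDP-glycosyltransferases at -0.10 (Ugt317A1 -0.72) and female fat body genes at -0.24 (Yp3 -0.39), which became -0.10 under quantile normalization. Phototransduction genes, at -0.01 (rdgB 0.53), and ribosomal protein genes, at -0.10 (RpL28 -0.36; 1.77th percentile with no matching on signal), had medians of 0.06 and 0.01 under quantile normalization.

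**Figure D3:**
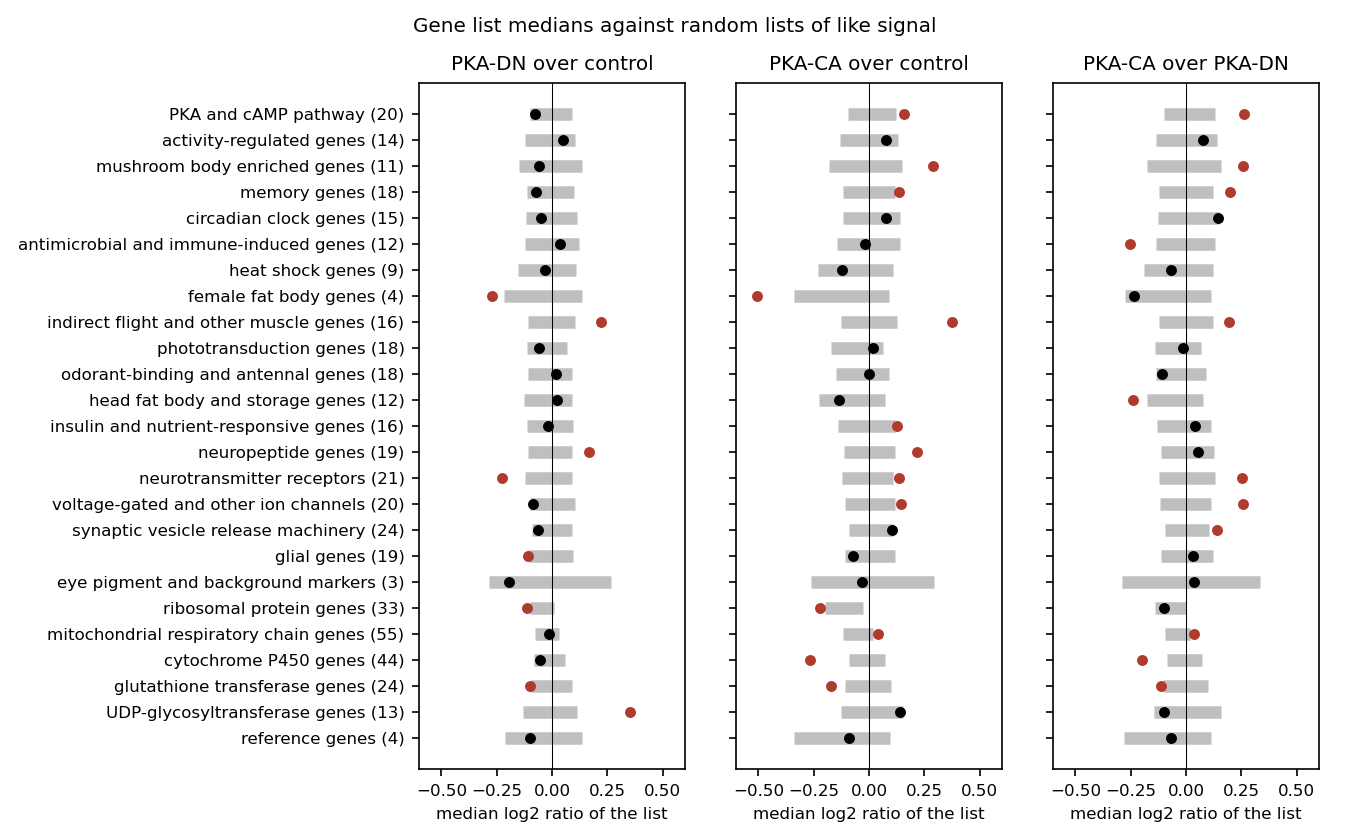
Median log2 ratio (points) of each of 25 gene lists in the 3 comparisons, with the number of members in brackets; grey bars span the central 95% of 10000 random lists matched on signal, and points outside them are red. The receptor and ion channel lists lie to the right for PKA-CA over PKA-DN (0.25 and 0.26) and the P450 list to the left (-0.20); quantile normalization turns the ribosomal (0.01), phototransduction (0.06) and reference gene (0.05) medians of that comparison positive.

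Over all 75 medians of 25 lists, 33 lay outside the range of random lists. By chance 3.75 would, if lists and the genes within them were independent. Some lists share members, and genes of 1 list can vary together between single arrays. The ratios of PKA-CA over PKA-DN also follow from those of the other comparisons. Setting 33 against 3.75 therefore does not measure an excess over chance. In PKA-DN over control 3 lists were above and 5 below the range, in PKA-CA over control 9 and 4, and in PKA-CA over PKA-DN 8 and 4. Muscle (0.22 and 0.37) and neuropeptide genes (0.17 and 0.22) lay above the range on both PKA arrays over control. Female fat body (-0.27 and -0.51), ribosomal protein (-0.11 and -0.22) and glutathione transferase genes (-0.10 and -0.17) lay below it on both. Receptor genes went opposite ways (-0.22 and 0.13). Both ratios share the control array, so a shift alike on both cannot be told apart from a state of that array. With length matched as well, 25 medians were outside, and 26 with finer strata of length. The 5 other lists had too few bright members: the Turandot stress genes had 1 in the upper 50%, the ovary genes 1, and the male reproductive tract, gut enzyme and roX lists 0. Their brightest members were TotC at 1903, 2122 and 2526 on the control, PKA-DN and PKA-CA arrays, Cp18 at 278, 248 and 256, and Acp95EF at 170, 136 and 123, and no roX probe set was named.

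A transcript that follows PKA activity in steps would have the control between PKA-DN and PKA-CA. Very few did. No gene went from low in PKA-DN to high in PKA-CA with both steps of 1.5-fold or more, and 3 went the other way: CAH5, with signals of 593 in PKA-DN, 380 in control and 122 in PKA-CA, CG18343 with 1241, 824 and 213, and the P450 gene Cyp4ac2 with 495, 304 and 199. With PKA-DN in the middle there were 2, Prx6c, highest in PKA-CA, and CG34456, highest in the control. With PKA-CA in the middle there were 5, CG3348, CG8539, DptB and alpha-Est2, highest in PKA-DN, and CG33296, highest in the control. These counts of 3, 2 and 5 are close to each other, as they would be if the order of the arrays were arbitrary. With quantile normalization or cyclic loess 1 gene had PKA-DN in the middle, and with 16 added to each signal 1 had the control in the middle.

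Several genes differed from the control on both PKA arrays in the same direction. At 2-fold these were Zip102B, Pepck2 and Obp99a, which were higher, and CG34456, e, Pgant4, CG34227, PPO1 and PPO2, which were lower. At 1.5-fold 28 genes were higher and 24 lower on both arrays, and no gene was 2-fold higher on 1 and 2-fold lower on the other. Simulated unchanged groups sharing a control gave means of 29.2 and 29.3 at 1.5-fold and of 4.59 and 5.17 at 2-fold, while independent lists would share 1.53 and 1.62 at 1.5-fold. Across genes the ratios of the PKA arrays over control had a Pearson correlation of 0.42 (simulated 0.50, range 0.46 to 0.53) and a covariance of 0.0288 (simulated 0.0363, range 0.0317 to 0.0417), and 62.9% of genes had the same sign (simulated 66.6%). The control could not be split, and part or all of the excess over independent lists may come from the shared control. Simulated means at 1.5-fold were no lower than the counts observed. The simulated noise came from these same arrays, however, and holds any real shared change, so these counts cannot tell the causes apart. The observed correlation, covariance and percentage with the same sign (lowest simulated 64.6%) all lay below the simulated ranges. The simulation therefore did not reproduce these arrays.

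Separate probe sets of a gene give a check within each array. For 304 genes with at least 2 bright probe sets the correlation of their log2 ratios was 0.365 for PKA-DN over control, 0.244 for PKA-CA over control and 0.27 for PKA-CA over PKA-DN. Of the genes past 1.5-fold by the brightest probe set, 6 of 8, 7 of 11 and 14 of 18 had the same sign in the other. In the bulk of genes differences were small: 97.1%, 96.4% and 95.8% lay within 1.5-fold, with an SD across genes of 0.25, 0.27 and 0.28. The counts of genes past 2-fold depended on the signal filter: without it, 871 genes were higher and 844 lower in PKA-DN over control, and in the upper 25% by signal 10 and 8.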

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

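The tests on blood cells, on neural tissue, on signal and on gene length, and the unions of neuronal lists, were chosen after list medians and gene values had been seen, as were the genes Hml, NimC1 and lz. Probe sets that have no single gene name were outside the comparisons of named genes, and some of them differed strongly from the control. Of 5123 such probe sets 847 were in the upper 50% by signal, and 10 of these were at least 2-fold higher in PKA-DN than in control and 8 in PKA-CA. The signal of the probe set with the highest PKA-DN ratio went from 201 on the control array to 4227 on the PKA-DN array (21.1-fold), and that of the probe set with the highest PKA-CA ratio from 431 to 9406 on the PKA-CA array (21.8-fold). Both exceed the ratio of any named gene compared. The lowest log2 ratios were -2.13 in PKA-DN and -1.57 in PKA-CA. Between the PKA arrays 10 were higher in PKA-CA and 7 lower, and the lowest, at -4.01 (16.1-fold), had 129, 2039 and 127 on the control, PKA-DN and PKA-CA arrays, also beyond any named gene compared. The sources used here give neither the genes of these probe sets nor the coding sequences of the transgenes.

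Neuropeptides (0.06), activity-regulated genes (0.08) and circadian clock genes (0.15) lay within the range of random lists for PKA-CA over PKA-DN. The first pattern weighed was that 6 other lists of neuronal genes were higher in PKA-CA than in PKA-DN. The 107 genes of these lists had a median of 0.24, against 0.004 for random lists matched on signal (upper end of their range 0.053). Each of the 6 lists had been taken because it lay above such a range, so this cannot test a trend with signal. Random lists matched on length too, in finer strata, had a median of 0.11 (upper end 0.16), so length may account for part of the pattern. Whether it accounts for all of it is not decided, because the lists were chosen for high medians. Because the 6 lists had been taken for their high medians, all 9 lists of neuronal genes were also joined. Their median was 0.16, at percentile 100 in both matchings. However, 107 of the 153 genes joined are those of the 6 lists. The joined median is therefore not independent of that choice and does not settle the part of signal or length. Singly, receptors (99.1) and ion channels (97.6) lay above the length-matched range. The PKA (94.5), mushroom body (94.4), memory (96.8), vesicle release (83.0), neuropeptide (81.8), activity-regulated (78.2) and clock lists (93.3) lay within it. A larger share of neural tissue in the PKA-CA heads would lower the other tissues alike: head fat body (-0.24, percentile 0.2) and female fat body genes (-0.24, 5.52) were lower and phototransduction genes were at -0.01 (0.06 under quantile normalization), but muscle genes were higher, at 0.20 (percentile 99.83, or 99.2 without the synaptic gene Sap47; 0.09 in the upper 25% by signal), which argues against that share as the only difference in tissue. Less fat body, a difference between single RNA preparations and an effect of PKA itself stay open and were not tested.

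The second pattern was that 52 genes differed by 1.5-fold or more in the same direction on both PKA arrays. Differing genetic backgrounds around a few sites would place such genes close together. In this set 4 pairs lay within 10 compared genes of each other, against a mean of 4.43 in 1000 random sets (percentile 45.85). The upper end of the random range was 9 pairs. A background of 1 PKA line alone would not show in this set. In PKA-DN over control 175 genes made 67 pairs, against a random mean of 50.3 (percentile 98.95). The random sets were matched on mean signal only, not on families of related genes, so that count does not single out backgrounds. Differing backgrounds therefore stay open. Noise or an unusual state of the control array gives the same pattern and cannot be told apart from a shared effect of the transgenes, because all 52 genes are also genes on which the control stands apart. Spike-in controls also differed from the control array in the same direction on both PKA arrays, but they do not tell the causes apart for these genes. Estimated from the covariance of the ratios, the deviations of the control array had a variance of 0.0288, against 0.0348 for PKA-DN and 0.0453 for PKA-CA. The estimate holds only if the transgenes have unrelated effects, and the PKA variances also hold any such effects. These values therefore do not decide whether the control was the most deviant array.

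The third pattern was the low signal of PPO1 and PPO2 on both PKA arrays. Fewer blood cells of all kinds would lower other blood cell genes about as much. Averaged over both arrays, 11 of them, among them Hml and NimC1, had a median of -0.047, and the lowest was NimC1 at -0.50. That average joins lower values in PKA-DN (median -0.34) with higher ones in PKA-CA (0.15), so it cannot decide for PKA-DN. Fewer blood cells in PKA-DN therefore stay open. In PKA-CA the lowest of the 11 was NimC1 at -0.22, against -1.36 for PPO1 and -1.46 for PPO2. This argues against a loss of all kinds as large as the fall of those genes there, while a smaller loss stays open. Some of the 11, such as the collagen genes, are also expressed in other tissues, which could hide part of a loss. Hml and NimC1 were lower in PKA-DN, at -0.39 and -0.77, than in PKA-CA, at -0.08 and -0.22. PPO1 and PPO2 belong to crystal cells; lz, a transcription factor gene of that cell type and of the eye, had 0.10 in PKA-DN and 0.26 in PKA-CA, but 1 gene does not settle whether crystal cells alone were lost, and an effect of PKA was not tested.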

How the results depend on the processing

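Random lists matched on gene length, and their finer strata of length, were chosen after a trend with length had been seen. Averaging the probe sets of a gene turned the PKA-DN over control ratios of Mlp60A and Rbp to -0.0024 and 0.48, since their other probe sets are dimmer and differ in sign. That of Rbp had a mean signal of 2.72, below the highest negative control. Of the 36, 27 and 42 genes past 2-fold in PKA-DN over control, PKA-CA over control and PKA-CA over PKA-DN, quantile normalization kept 35, 26 and 40, cyclic loess 34, 27 and 39, and centring 34, 25 and 41. Quantile normalization and cyclic loess each left 1 gene with PKA-DN in the middle, for a cause that was not tested. Adding 16 left 1 gene with the control in the middle; adding 64, which shrinks ratios of dim genes by construction, left 0, 1 with PKA-DN in the middle, and 9 genes higher in PKA-CA than in PKA-DN. With no signal filter, which admits probe sets near background, 871 genes were higher and 844 lower in PKA-DN over control, 652 and 1179 in PKA-CA over control, and 659 and 1194 in PKA-CA over PKA-DN; the counts with control, PKA-DN and PKA-CA in the middle were 323, 327 and 366, and the covariance was 0.375. The upper 25%, with fewer genes tested, gave 10 and 8, 6 and 4, 10 and 7, and middle counts of 0, 0 and 3. At 1.5-fold the counts were 89 and 86, 103 and 113, and 133 and 120, and 2-fold steps left 0, 1 and 0 ordered genes. For the PKA list, the PKA-CA over PKA-DN median was 0.18 with no filter and 0.19 in the upper 25%. Averaging probe sets gave 0.027, 0.099 and 0.062 in the 3 comparisons, so the negative sign for PKA-DN was seen with the brightest probe sets only. The average brings in probe sets below the highest negative control, such as those of nej (mean signal 18.2), Epac (31.6) and Pka-R1 (7.39). Brighter ones of Pde9 also had positive ratios in PKA-DN, at 0.14 and 0.49, but one of Pde1c had -0.57. Matching on length put its PKA-CA over control percentile at 93.5, and with finer strata at 91.7, with 94.5 for PKA-CA over PKA-DN. Of all list medians recomputed, 536 moved by less than 1 SD of random medians and 61 by more. Of named gene ratios 2212 moved by less than the spread across genes of like signal and 72 by more. Those of Mlp60A and Rbp were counted apart, as ratios past 1.5-fold that changed sign. Other changes of sign are within the 2212 and the 72. In all 36 changed sign, 21 of them with probe sets averaged, and of these only Mlp60A and Rbp had been past 1.5-fold. Signals near the negative controls, such as Zip102B in the control and Cyp4g1 in PKA-CA, limit those folds.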

Other observations

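The test on oenocytes was chosen after the values of Cyp4g1 had been seen, as were the other genes named here. Genes set apart in PKA-DN were more often neighbours than random genes. Neighbours were genes within 10 genes of each other on a chromosome, counting only the genes compared. Among the 175 genes that differed by 1.5-fold or more from the control in PKA-DN, 67 pairs were neighbours. Random sets matched on mean signal, but not on gene family, had a mean of 50.3 pairs, which put 67 at percentile 98.95. In PKA-CA over control 216 genes made 83 pairs (percentile 77.25) and in PKA-CA over PKA-DN 253 genes made 117 (percentile 88.5).

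Less oenocyte RNA in the PKA-CA sample would lower Cyp4g1 together with other oenocyte genes. Of 12 such genes 3, spidey at -0.18, Hnf4 at -0.10 and bond at -0.10, were in the upper 50%, with a median of -0.102 in PKA-CA over control against -3.33 for Cyp4g1. That is above the limit of -0.5 set for this test, which was a wrong one for these genes, since the other 9 lay below the highest negative control on both arrays, and in whole heads Hnf4 and spidey also come from tissues such as fat body, which would hide the loss of a small oenocyte share. Less oenocyte RNA and a change in Cyp4g1 itself therefore cannot be told apart.

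Blood cell genes were on the whole lower in PKA-DN than in PKA-CA, a difference seen after the marker list was drawn up for another purpose. The median of 11 genes was -0.34 for PKA-DN over control, 0.15 for PKA-CA over control and 0.39 for PKA-CA over PKA-DN, with the collagen genes vkg at 0.70 and Col4a1 at 0.61 in the last. Head fat body and other tissues also express collagens.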
